A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

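RNA of budding yeast (Saccharomyces cerevisiae) was measured on 14 Agilent 2-colour arrays that lay on 2 slides, 6 arrays on the first and 8 on the second. Each array compared a pair of RNA samples, 1 labelled with Cy3 and 1 with Cy5. Per the labels, cells grew in synthetic complete medium lacking leucine, isoleucine and valine. The drug sulfometuron methyl (SM) was given for 2 h where a sample is called treated. Fresh cultures were inoculated in duplicate from a pre-culture, and taf9-tCRD2 cells started at a higher density than wild type (WT). The labels call each array a biological replicate but do not say whether each array had its own cultures, so the p-values here measure only the spread between these arrays.

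The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 10.7.3.1: the mean signal, the median local background and the processed signal of every spot as intensity in each dye, and the ratio of the processed signals as log10. In the deposited values there is a single log2 ratio per probe and array. Tested on the files, it lay within 0.01 of the scanner's log10 ratio changed to base 2 for 95.7% to 98.3% of the spots of an array, with the sign turned on the 7 arrays whose Cy5 channel held the untreated or WT RNA. Of the other spots 73.2% to 89.2% had a scanner ratio of 0 and another value in the table. It was not centred further, as the medians of its columns lay between -0.037 and 0.042. Probe coordinates are those of the array design, build sacCer1. No genome sequence was at hand, so the planned lists based on sequence motifs were not made.

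The ratios reported here were computed again from the mean signals and median backgrounds with limma 3.58.1 in R 4.3.3, with the packages data.table (1.17.8) and jsonlite (2.0.0) for input. Background was corrected by the normexp method with an offset of 50, which pulls the ratios of dim probes toward 0. Each array was normalized within itself by loess over its brightness range, with no weight on control spots. This sets the typical gene to no change, so a shift of all mRNA together cannot be seen. Spots that Feature Extraction marked as outliers were left out, 1.84% to 2.50% of the spots of an array, and the remaining spots of a probe were averaged. Each array held 15744 spots, of which 15208 were not controls, with 2 to 8 spots per probe. A probe was kept if it was well above background in either dye on every array of at least 1 group, which left 6019 of 6227 probes, called genes from here on. Of these, 5997 had a value on every array and 22 lacked 1 on some array. The reference paired 5738 locus tags with current symbols.

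The median signal of an array ranged from 734 to 2200 in Cy3 and from 527 to 2090 in Cy5. Between 88.8% and 96.6% of the probes of an array were well above background, and at most 106 probes were saturated in a channel. Replicate spots of 1 probe had a standard deviation (SD) of 0.07 on the log2 scale, while the residual SD of whole arrays ran from 0.08 to 0.28. Where the brighter channel was saturated, or the dimmer one was not well above background, the fold is given as a lower bound and written "at least N-fold". A few probes belong to near-identical gene families and cannot tell their members apart, and this is said where they are named.

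The arrays form 4 groups: WT with against without SM (4 arrays), taf9-tCRD2 with against without SM (4), taf9-tCRD2 against WT, both with SM (4), and spt20D against WT, both with SM (2). All 14 were fitted together in limma with 1 coefficient per group and a dye term for each gene, which left 9 residual degrees of freedom plus 4.26 from the moderated variance. The second group minus the first is the difference in SM response. The first minus the second plus the third is the indirect difference between untreated taf9-tCRD2 and WT cells. The fourth minus the third is the difference between the effects of both mutations. The p-values, for a change in either direction, were adjusted over all genes by Benjamini and Hochberg's method, and a gene with an adjusted p under 0.05 is said to have risen or fallen. Genes were named by a rule: in each of the 4 groups, the 8 highest and 8 lowest of the standard-named genes that passed and had the same sign on every array, and in each derived contrast 4 of each. Added were up to 3 passing members with the lowest adjusted p of each gene list that passed, and always TAF9, SPT20, GCN4, ILV2, HIS4, ARG1, SNZ1 and the genes used as auxotrophic markers. Not everything that this rule takes in is reported here.

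Altogether 36 gene lists of pathways, complexes and cell type markers were tested with limma's camera, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, and with fry. Camera asks whether the genes of a list moved more than the other genes. The p of fry asks whether the genes of a list moved on balance in 1 direction, without comparing them with other genes. Those p-values were adjusted over the lists. The comparisons, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for 1 alternative that averages the dye-swapped arrays of a slide. Shares of genes carry exact binomial 95% intervals, which treat genes as independent and cover counting error only.

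Because the spt20D arrays and the third group were both measured against WT RNA with SM, noise in that RNA moves both alike. The overlap without mutant effects was measured in 100 simulated data sets, with noise of the arrays' size in the RNA. It includes false calls where arrays of 1 RNA share that noise. The fit was also tested on simulated data in which known genes were moved by 1.5-fold to 4-fold. With 4 arrays it found 59 of 67 genes moved 1.5-fold and 65 of 67 moved 2-fold, and called 7 of 5789 unchanged genes. With 2 arrays it found 37 of 67 and 62 of 67, and called 9 unchanged genes. Noise was drawn separately for each array here, so these rates hold only if the arrays are independent. The alternatives were Feature Extraction's own ratios, no background correction, median centring in place of loess, scaling between arrays, the deposited table, other filters, outlier spots kept, no dye term, a fit of only the arrays of a contrast, an intensity trend with robust variances, the slide or the replicate number as a block, each slide alone, fold minimums and leaving out each array. Among the 3 groups of 4 arrays, residuals of same-numbered arrays correlated between -0.21 and 0.70. Shared RNA can give either sign, so whether numbers pair the arrays stays open. Within a group, residual correlations ran from -0.24 to 0.47 on a slide and from -0.85 to -0.30 across slides. Arrays of a slide may not be independent, and p-values may be too small.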

Results

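The series asked which yeast genes depend on the conserved C-terminal region of Taf9, a protein shared by the transcription complexes TFIID and SAGA, and which depend on Spt20, a subunit that SAGA needs to stay whole. Cells were studied under amino acid starvation. Sulfometuron methyl (SM) blocks the enzyme that ILV2 encodes and thereby starves cells of isoleucine and valine, a condition in which the transcription factor Gcn4 is made. RNA abundance was compared on 14 2-colour arrays: 4 of wild type (WT) with against without SM, 4 of the mutant taf9-tCRD2 with against without SM, 4 of taf9-tCRD2 against WT in SM, and 2 of the deletion mutant spt20D against WT in SM. The first slide held 2 arrays of each of the first 3 groups, and the other held the remaining 8 arrays, both spt20D arrays among them. In total 6019 genes were tested. Values are log2 ratios, given as mean ± SD over the arrays of a group with adjusted p-values from limma. For spt20D the SD is over 2 dye-swapped arrays, and the p-values rest mostly on the spread of the other groups. For derived contrasts the standard error (SE) is given instead.

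SPT20 RNA was at least 13.3-fold lower in spt20D than in WT (log2 -4.51 ± 0.21, n = 2, adjusted p = 2.47e-12), and its signal in spt20D was not well above background. In taf9-tCRD2 it stood at 0.07 ± 0.15 and did not pass (n = 4, adjusted p = 0.472). Its probe covers bases 45779 to 45838 of the minus strand of chromosome XV, starting at base 1735 of the gene (YOL148C). TAF9 RNA was 9.94-fold higher in taf9-tCRD2 than in WT in SM (3.31 ± 0.33, n = 4, adjusted p = 5.95e-10). The TAF9 probe covers bases 743262 to 743321 of the plus strand of chromosome XIII, starting at base 292 of the gene (YMR236W). The labels do not say which part of TAF9 is missing, so this value measures the RNA and not the truncation. TAF9 also stood at 0.58 ± 0.03 in spt20D (n = 2, adjusted p = 0.018), but this was lost on the second slide alone (adjusted p = 0.0721) and without either array (adjusted p = 0.103 and 0.215).

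The strains differed in marker genes as well. URA3, a pyrimidine synthesis gene often used as a marker, fell by 4.31 ± 0.12 in taf9-tCRD2 (n = 4, adjusted p = 1.42e-13) and by 5.30 ± 0.01 in spt20D (n = 2, adjusted p = 9.03e-13), and on the arrays of taf9-tCRD2 with against without SM it was not well above background in either channel. LEU2, a leucine synthesis gene, rose by 2.68 ± 0.19 in taf9-tCRD2 (n = 4, adjusted p = 1.8e-08) and fell by 6.94 ± 0.48 in spt20D (n = 2, adjusted p = 3.01e-11), although the labels give the same medium lacking leucine for all strains. The spt20D strain or its medium may therefore not be as labelled, which bears on all amino acid genes in spt20D. Each genotype was a single strain, so effects of the mutation and of the strain's background were measured together.

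The first comparison asked how WT cells respond to SM. RTC2, a vacuolar transporter of basic amino acids, rose 33.0-fold (5.05 ± 0.21, n = 4, adjusted p = 8.35e-12), STR3 of sulfur amino acid metabolism rose 26.0-fold (4.70 ± 0.11, adjusted p = 3.16e-13), and SNZ1 of vitamin B6 synthesis rose 20.7-fold (4.37 ± 0.31, adjusted p = 3.31e-11). ARO9, an aromatic aminotransferase, rose by 4.25 ± 0.17, ARG4 of arginine synthesis by 4.20 ± 0.39, the sulfite exporter gene SSU1 by 4.10 ± 0.41, and the nitrilase gene NIT1 by 4.04 ± 0.12. DBP2, an RNA helicase gene, fell 21.8-fold (-4.44 ± 0.59, adjusted p = 1.25e-10), and TAT1, an amino acid permease gene, fell 19.3-fold (-4.27 ± 0.23, adjusted p = 1.94e-13). The pyrimidine synthesis gene URA1 stood at -4.18 ± 0.67, the adenine deaminase gene AAH1 at -3.96 ± 0.73, the hexose transporter gene HXT2 at -3.39 ± 0.85, and the acid phosphatase gene PHO3 at -3.23 ± 0.25, and each of these fell. GCN4 itself rose by 1.17 ± 0.31 (adjusted p = 4.27e-07), ILV2 by 1.59 ± 0.35 (adjusted p = 2.8e-08), and TAF9 by 1.13 ± 0.26 (adjusted p = 2.11e-06).

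In each list below the counts are genes that rose, fell or did not pass over all genes, with the count adjusted within the list where it differed. The p-values of lists come from camera, first with the preset and then with an estimated correlation, and medians on slide 1 and slide 2 alone stand in that order. All 10 arginine synthesis genes rose with SM in WT (median 2.89, slides 2.85 and 2.97, adjusted p = 1.61e-06). The arginine list had adjusted p = 0.0749 with an estimated correlation. All 8 lysine synthesis genes did so too, among them LYS1 (3.89 ± 0.27) and LYS20 (2.97 ± 0.43), with a median of 2.17 (slides 2.24 and 2.11, adjusted p = 3.55e-05). The lysine list had adjusted p = 0.226 with an estimated correlation. Of 6 histidine synthesis genes 5 rose and 1 did not pass, while adjusted within the list 5 rose and 1 fell (median 2.32 on both slides and in all, adjusted p = 0.0044). The histidine list had adjusted p = 0.226 with an estimated correlation. Its members HIS5 and HIS4 stood at 3.75 ± 0.17 and 3.74 ± 0.15, the latter saturated and at least 13.4-fold higher. Of 13 aromatic amino acid genes 12 rose and 1 fell (median 1.34, slides 1.39 and 1.36, adjusted p = 0.000156). The aromatic list had adjusted p = 0.226 with an estimated correlation. Of 35 other genes that Gcn4 is known to activate, 31 rose, 1 fell and 3 did not pass, and adjusted within the list 32 rose and 1 fell (median 1.89, slides 2.19 and 1.89, adjusted p = 1.37e-09). The other Gcn4-activated list had adjusted p = 0.0749 with an estimated correlation. Of 22 sulfur amino acid genes 16 rose and 6 fell (median 1.02, slides 1.08 and 1.02, adjusted p = 0.00238). The sulfur list had adjusted p = 0.241 with an estimated correlation. The list of 12 branched-chain amino acid synthesis genes did not pass (8 rose, 2 fell and 2 did not pass, median 0.96, slides 0.88 and 1.01, adjusted p = 0.0603). The branched-chain list had adjusted p = 0.411 with an estimated correlation.

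Genes that nitrogen catabolite repression holds down in rich nitrogen also rose with SM in WT, 20 of 26, with 4 that fell and 2 that did not pass (median 0.95, slides 0.96 and 1.01, adjusted p = 0.00034). That list had adjusted p = 0.389 with an estimated correlation. Its members AMD2 and the glutamate dehydrogenase gene GDH2 rose by 2.98 ± 0.15 and 2.81 ± 0.19. Of 18 amino acid permease genes 13 rose, 1 fell and 4 did not pass (median 0.96, slides 0.82 and 1.10, adjusted p = 0.00217). The permease list had adjusted p = 0.1 with an estimated correlation. AGP1, a permease of broad range, rose by 2.66 ± 0.26. Genes of the environmental stress response, which rise under many stresses, rose in 43 of 53 cases and did not pass in 10, and adjusted within the list 43 rose and 1 fell (median 1.27, slides 1.47 and 1.20, adjusted p = 9.28e-07). The stress response list had adjusted p = 0.524 with an estimated correlation. Among them were the heat shock protein genes HSP12 (3.85 ± 0.44) and HSP78 (3.22 ± 0.48). Of 7 genes expressed only in cells of mating type a, all 7 rose (median 1.38, slides 1.34 and 1.40, adjusted p = 0.00238, or 0.226 with an estimated correlation), among them ASG7 (2.31 ± 0.29) and the a-factor exporter gene STE6 (1.45 ± 0.23). Of 18 haploid and pheromone-induced genes 13 rose, 2 fell and 3 did not pass (median 1.20, slides 1.18 and 1.22, adjusted p = 0.00238). That list had adjusted p = 0.226 with an estimated correlation.

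The machinery of ribosome production fell with SM in WT. All 102 ribosome biogenesis genes fell (median -1.70, slides -1.49 and -1.96, adjusted p = 5.59e-19, or 0.411 with an estimated correlation), among them SDA1 (-2.77 ± 0.62) and ENP1 (-2.39 ± 0.51). Of 137 ribosomal protein genes 109 fell, 7 rose and 21 did not pass, and adjusted within the list 110 fell (median -1.08, slides -1.11 and -1.05, adjusted p = 2.77e-12). The ribosomal protein list had adjusted p = 0.433 with an estimated correlation. RPS22B and RPS9A, both for proteins of the small subunit, stood at -3.29 ± 0.30 and -2.18 ± 0.26. Of 19 genes for subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, 18 fell and 1 did not pass (median -1.36, slides -1.25 and -1.47, adjusted p = 2.32e-06, or 0.411 with an estimated correlation). RPC31 was among them (-1.95 ± 0.16). Of 28 translation factor genes 24 fell, 2 rose and 2 did not pass, and adjusted within the list 3 rose (median -1.12, slides -1.04 and -1.05, adjusted p = 3.23e-06). The translation factor list had adjusted p = 0.313 with an estimated correlation. Over all genes 2388 rose and 2193 fell, a total of 4581 (4650 with the slide as a block, 4709 on slide 1 and 3941 on slide 2), and 718 rose and 700 fell by at least 2-fold. Camera called 18 of the 36 lists, and with an estimated correlation 0, although 7 had an unadjusted p under 0.05.

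The next comparison asked how taf9-tCRD2 cells respond to SM. SNZ1 rose at least 37.7-fold (5.35 ± 0.43, n = 3, saturated, adjusted p = 3.82e-11), STR3 19.5-fold (4.28 ± 0.14, n = 4, adjusted p = 1.04e-12) and ARG4 17.4-fold (4.12 ± 0.31, adjusted p = 1.03e-12). PRM5, a cell integrity gene, rose by 3.99 ± 0.31, RTC2 by 3.86 ± 0.49, ICY2 by 3.84 ± 0.36, SSU1 by 3.79 ± 0.37 and ARG5,6 of arginine synthesis by 3.75 ± 0.21. HO, the endonuclease gene of mating type switching, fell 14.4-fold (-3.85 ± 0.07, adjusted p = 3.5e-13). The alcohol dehydrogenase gene ADH4 stood at -3.20 ± 0.67, the glutamate dehydrogenase gene GDH1 at -3.11 ± 0.09, the ribonucleotide reductase gene RNR1 at -2.68 ± 0.13, the iron transporter gene SIT1 at -2.65 ± 0.23 and the nuclear transport gene GSP1 at -2.62 ± 0.36, and each of these fell. GCN4 rose by 1.13 ± 0.31 (adjusted p = 8.93e-07) and ILV2 by 2.20 ± 0.20 (adjusted p = 1.78e-09). ARG1 was saturated with SM and rose at least 2.10-fold (1.07 ± 0.22, n = 3, adjusted p = 5.97e-05), but stood at -0.075 with median centring in place of loess.

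The amino acid groups rose in this mutant too. All 10 arginine genes (median 2.67, slides 2.68 and 2.58, adjusted p = 4.07e-07, or 0.0541 with an estimated correlation) and all 8 lysine genes rose (median 2.35, slides 2.54 and 2.16, adjusted p = 9.18e-06). The lysine genes had adjusted p = 0.208 with an estimated correlation. Of 6 histidine genes 5 rose and 1 fell (median 2.37, slides 2.41 and 2.33, adjusted p = 0.00591). The histidine list had adjusted p = 0.246 with an estimated correlation. Of the 35 other Gcn4-activated genes 31 rose, 1 fell and 3 did not pass (median 1.94, slides 1.81 and 1.78, adjusted p = 2.97e-10). That list had adjusted p = 0.0541 with an estimated correlation. Of 12 branched-chain genes 10 rose, among them the dehydratase gene ILV3 (1.45 ± 0.16), 1 did not pass, and LEU1 of the leucine branch fell by 1.74 ± 0.29 (median 0.73, slides 0.74 and 0.71, adjusted p = 0.0135). The branched-chain list had adjusted p = 0.276 with an estimated correlation. The a-cell genes all rose (7 of 7, median 1.34, slides 1.29 and 1.39, adjusted p = 0.0016, or 0.241 with an estimated correlation), the pheromone receptor gene STE2 by 1.84 ± 0.25. Of 20 genes that heat shock factor activates 13 rose, 1 fell and 6 did not pass, among them the chaperone genes HSP82 (1.51 ± 0.55) and SIS1 (1.43 ± 0.09), and the list's median of 0.59 (slides 0.61 and 0.70, adjusted p = 0.0187, or 0.513 with an estimated correlation) became -0.11 with median centring.

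Ribosome biogenesis genes fell in 74 of 102 cases in taf9-tCRD2 with SM, with 28 that did not pass and 75 that fell adjusted within the list (median -0.66, adjusted p = 2.01e-08). That list had adjusted p = 0.654 with an estimated correlation. Their median was -0.24 on slide 1 and -1.04 on slide 2, and -0.39 without array 4 of the group. NOP1, a nucleolar RNA methyltransferase gene, fell by 2.06 ± 0.71 and DBP2 by 1.91 ± 0.34. Of 137 ribosomal protein genes 123 fell, 5 rose and 9 did not pass (median -1.02, slides -0.71 and -1.34, adjusted p = 3.71e-17, or 0.376 with an estimated correlation), and RPS11A fell by 2.07 ± 0.48. Of 19 polymerase I and III genes 16 fell and 3 did not pass (median -0.84, slides -0.55 and -1.07, adjusted p = 0.000139). The polymerase list had adjusted p = 0.513 with an estimated correlation. Stress response genes rose in 33 of 53 cases, 4 fell and 16 did not pass (median 0.64, slides 0.37 and 0.95, adjusted p = 0.00108, or 0.683 with an estimated correlation), and their median was 0.39 without array 4. Over all genes 2264 rose and 1977 fell, a total of 4241 (4345 with the slide as a block, 4266 on slide 1 and 3724 on slide 2), and 484 rose and 458 fell by at least 2-fold. Camera called 18 lists, and with an estimated correlation 0, although 7 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the responses of both strains correlated with r = 0.886 (0.855 on slide 1 and 0.876 on slide 2), and the slope of the mutant's response on that of WT was 0.72.

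**Figure D1:**
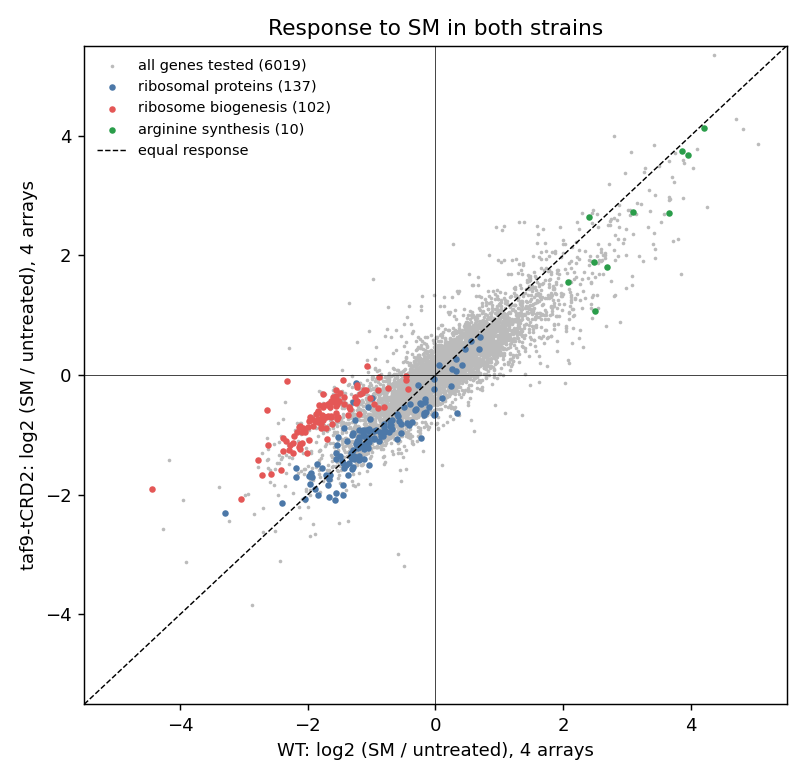
Each point is a gene, with its log2 ratio of SM over untreated in WT on the horizontal axis and in taf9-tCRD2 on the vertical axis, and colours mark the ribosomal protein, ribosome biogenesis and arginine synthesis lists. Ribosome biogenesis genes had a median of -1.70 in WT and -0.66 in taf9-tCRD2, while ribosomal protein genes had -1.08 and -1.02 and arginine genes 2.89 and 2.67.

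The difference between both SM responses was tested for genes that responded differently in the strains. The responses of URA1 (2.76, SE 0.29, adjusted p = 3.56e-05), the hexose transporter genes HXT4 (2.75, SE 0.59, adjusted p = 0.00471) and HXT3 (2.58, SE 0.42, adjusted p = 0.000953), and CIT2, a peroxisomal citrate synthase gene (2.56, SE 0.17, adjusted p = 2.84e-06), were higher in taf9-tCRD2. Those of ADH4 (-2.71, SE 0.25, adjusted p = 1.48e-05), the aldehyde dehydrogenase gene ALD3 (-2.17, SE 0.34, adjusted p = 0.000669), HSP12 (-2.16, SE 0.25, adjusted p = 7.52e-05) and the proline permease gene PUT4 (-2.03, SE 0.16, adjusted p = 6.47e-06) were lower. The response of ribosome biogenesis genes was higher in the mutant for 93 of 102 genes, that is, they fell less, and 97 passed adjusted within the list (median 1.06, slides 1.20 and 0.87, adjusted p = 2.46e-26). The ribosome biogenesis list had adjusted p = 0.495 with an estimated correlation. DBP2 (2.54, SE 0.26), NSR1 (2.23, SE 0.36) and NOG1 (2.06, SE 0.33), all of ribosome synthesis, were among them. Of 19 polymerase I and III genes 9 had a higher response and 10 did not pass, and 10 passed adjusted within the list (median 0.57, slides 0.66 and 0.49, adjusted p = 1.14e-05). The polymerase list had adjusted p = 0.495 with an estimated correlation. Of 20 heat shock factor genes 14 had a higher response, 16 adjusted within the list, and 6 did not pass (median 0.65, slides 0.64 and 0.68, adjusted p = 1.59e-06, or 0.495 with an estimated correlation), among them the chaperone gene YDJ1 (1.36, SE 0.13). For ribosomal proteins the median difference was -0.07, and it had opposite signs on the slides (0.25 and -0.41).

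Hexose transporter genes had a higher SM response in taf9-tCRD2 for 8 of 15 genes, with 7 that did not pass (median 0.42, slides 0.26 and 0.65, adjusted p = 0.00091). Purine synthesis genes did so for 7 of 18, with 2 lower and 9 not passing. Adjusted within the list 11 were higher and 2 lower (median 0.42, slides 0.48 and 0.44, adjusted p = 0.000918). Both lists had adjusted p = 0.495 with an estimated correlation. The stress response was weaker, with 21 of 53 genes lower, 1 higher and 31 not passing (median -0.56, slides -0.90 and -0.26, adjusted p = 6.59e-06). The stress response list had adjusted p = 0.619 with an estimated correlation. Of 32 respiratory chain genes 17 had a lower response and 15 did not pass, and 20 were lower adjusted within the list (median -0.48, slides -0.43 and -0.54, adjusted p = 1.53e-06). An estimated correlation gave adjusted p = 0.495. Of 26 nitrogen catabolite repression genes 12 were lower, 3 higher and 11 did not pass, and adjusted within the list 14 were lower (median -0.41, slides -0.58 and -0.16, adjusted p = 7.19e-05, or 0.495 with an estimated correlation), with GDH2 at -1.47 (SE 0.14). Of 10 arginine genes 6 had a lower response and 4 did not pass, with a median of -0.44 (slides -0.45 and -0.46, adjusted p = 0.00891, or 0.495 with an estimated correlation) that became 0.038 with scaling between arrays. Of 13 aromatic genes 6 were lower and 7 did not pass (median -0.24, slides -0.36 and -0.27, adjusted p = 0.00851). The aromatic list had adjusted p = 0.495 with an estimated correlation. Of 35 other Gcn4-activated genes 12 were lower, 3 higher and 20 did not pass, adjusted within the list 13 were lower and 4 higher, and the median of -0.27 (slides -0.36 and -0.18, adjusted p = 0.0244, or 0.495 with an estimated correlation) became 0.13 with scaling. This list's call was lost on slide 2 (adjusted p = 0.122) and without taf9-tCRD2 array 4 (-0.23, adjusted p = 0.0547). GCN4 did not differ in response (-0.04, SE 0.16, adjusted p = 0.89). Over all genes the response was higher for 804 and lower for 875, a total of 1679, but this count was 2495 on slide 1 and 572 on slide 2 (1959 with the slide as a block), 442 with scaling and 281 with dye-swapped pairs of a slide averaged. Camera called 16 lists, and with an estimated correlation 0, although 1 had an unadjusted p under 0.05.

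The direct comparison in SM asked which genes depend on the C-terminal region of Taf9 under starvation. Besides TAF9, URA1 and LEU2, the highest genes in taf9-tCRD2 were CIT2 (10.9-fold, 3.45 ± 0.22, n = 4, adjusted p = 2.4e-10), the cell wall protein gene HPF1 (10.2-fold, 3.35 ± 0.79, adjusted p = 2.75e-07), the zinc transporter gene ZRT1 (2.43 ± 1.47, adjusted p = 0.000274) and the glucose-repressed alcohol dehydrogenase gene ADH2 (2.03 ± 0.58, adjusted p = 7.34e-07). URA1 stood at 2.99 ± 0.44 (adjusted p = 1.55e-07). The plasma membrane protein gene HSP30 stood at 2.29 ± 1.14 (adjusted p = 0.0131), but did not pass without array 3 (adjusted p = 0.0658) or array 4 (adjusted p = 0.0711). The lowest genes besides URA3 were the a-specific ASG7 (12.5-fold lower, -3.64 ± 0.24, adjusted p = 4.06e-11), the phosphate transporter gene PHO84 (-2.97 ± 2.31, adjusted p = 0.000859), PRM1 and FUS1 of cell fusion in mating (-2.68 ± 0.08 and -2.56 ± 0.13), FAR1 of pheromone arrest (-2.48 ± 0.12), and SPL2 and PHO3 of phosphate metabolism (-2.05 ± 0.50 and -2.05 ± 0.32). GCN4 was 0.62 ± 0.34 higher (adjusted p = 0.000617). ILV2 (-0.04 ± 0.40, adjusted p = 0.799), HIS4 (0.17 ± 0.25, adjusted p = 0.24), ARG1 (0.15 ± 0.29, adjusted p = 0.365) and SNZ1 (0.31 ± 0.32, adjusted p = 0.0915) did not pass, and the probes of HIS4 and ARG1 were saturated.

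Mating genes were lower in taf9-tCRD2 in SM. Of 18 haploid and pheromone-induced genes 14 were lower, 1 higher and 3 did not pass (median -0.96, slides -0.97 and -1.01, adjusted p = 3.06e-08). That list had adjusted p = 0.0557 with an estimated correlation. Of 7 a-cell genes 5 were lower and 2 did not pass (median -1.12, slides -1.23 and -1.17, adjusted p = 4e-04, or 0.332 with an estimated correlation), among them the pheromone protease gene BAR1 (-1.89 ± 0.26) and STE6 (-1.21 ± 0.19). Ribosome biogenesis genes were higher in 83 of 102 cases, 90 adjusted within the list, with 19 that did not pass (median 0.66, slides 0.93 and 0.43, adjusted p = 2.91e-14, or 0.692 with an estimated correlation), DBP2 by 1.51 ± 0.71. RRP14 stood at 1.08 ± 0.39, with an adjusted p of 0.0593 on slide 2 alone. Of 19 polymerase I and III genes 9 were higher, 10 adjusted within the list, and 10 did not pass (median 0.33, slides 0.59 and 0.16, adjusted p = 0.004, but adjusted p = 0.0948 on slide 2). The polymerase list had adjusted p = 0.787 with an estimated correlation. Of 20 heat shock factor genes 14 were higher, 1 lower and 5 did not pass, and 2 were lower adjusted within the list (median 0.53, slides 0.34 and 0.67, adjusted p = 0.00186, or 0.595 with an estimated correlation), with the chaperone genes YDJ1 at 0.84 ± 0.12 and HSC82 at 0.73 ± 0.19. Of 10 histone genes 8 were higher, 1 lower and 1 did not pass (median 0.81, slides 0.83 and 0.82, adjusted p = 0.00186). The histone list had adjusted p = 0.595 with an estimated correlation. The core histone genes HTB2 and HHT2 were higher by 1.22 ± 0.13 and 0.67 ± 0.14, and the linker histone gene HHO1 fell by 0.86 ± 0.17. In WT these genes fell with SM in 8 of 10 cases, with 2 that did not pass (median -0.52, slides -0.57 and -0.48, adjusted p = 0.03, or 0.411 with an estimated correlation).

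Of 15 hexose transporter genes 9 were higher in taf9-tCRD2 in SM, 1 lower and 5 did not pass, and adjusted within the list 10 were higher and 2 lower (median 0.46, slides 0.32 and 0.76, adjusted p = 0.004). That list had adjusted p = 0.595 with an estimated correlation. HXT3 stood at 1.97 ± 0.17 and HXT6, whose probe shares a near-identical family, at 1.88 ± 0.88. Of 18 purine genes 10 were higher, 1 lower and 7 did not pass, and 12 were higher adjusted within the list (median 0.43, slides 0.62 and 0.37, adjusted p = 0.000857, or 0.595 with an estimated correlation), among them IMD3 (1.13 ± 0.28) and ADE17 (1.00 ± 0.10). Of 26 nitrogen catabolite repression genes 11 were lower, 2 higher and 13 did not pass (median -0.23, slides -0.29 and -0.21, adjusted p = 0.00186, or 0.595 with an estimated correlation), with AMD2 at -0.97 ± 0.08. The branched-chain list held genes that moved apart: 6 were lower, 1 higher and 5 did not pass, 7 being lower adjusted within the list (median -0.30, adjusted p = 0.0357). The branched-chain list had adjusted p = 0.595 with an estimated correlation. The aminotransferase gene BAT2 (-1.69 ± 0.24) and the mitochondrial carrier gene OAC1 (-0.76 ± 0.24) were lower and ILV5 (1.13 ± 0.33) was higher. This call was lost on slide 1 (median -0.15, adjusted p = 0.366, against -0.34 on slide 2) and without array 3 (-0.23, adjusted p = 0.0525) or array 4 (-0.21, adjusted p = 0.116). The gluconeogenesis list, with 10 genes higher, 3 lower and 7 not passing (median 0.27, slides 0.06 and 0.51, adjusted p = 0.0236, or 0.692 with an estimated correlation), lost its call on slide 1 (adjusted p = 0.488) and without array 3 (0.23, adjusted p = 0.0795) or array 4 (0.21, adjusted p = 0.1). The glycolysis list had 6 of 19 genes higher and 13 not passing (median 0.10, slides 0.15 and 0.04, adjusted p = 0.0357). The glycolysis list had adjusted p = 0.595 with an estimated correlation. Its median became -0.0096 without the second array (adjusted p = 0.067) and 0.16 without any 1 of the others (adjusted p = 0.0841 without array 4).

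The lists of other Gcn4-activated genes and of arginine genes did not pass in taf9-tCRD2 in SM. Of the 35 other Gcn4-activated genes 8 were higher, 8 lower and 19 did not pass, with a mean of 0.08 and a median just below 0 (adjusted p = 0.962). Of the 10 arginine genes 5 were higher, 6 adjusted within the list, 2 lower and 3 did not pass (median 0.30, adjusted p = 0.15). Over all genes 1306 were higher and 1342 lower, a total of 2648 (2931 with the slide as a block, 3377 on slide 1 but 1517 on slide 2, and 1589 with dye-swapped pairs of a slide averaged), of which 87 were higher and 124 lower by at least 2-fold. Camera called 12 lists, and with an estimated correlation 0, although 2 had an unadjusted p under 0.05.

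Untreated taf9-tCRD2 and WT cells were compared only indirectly, through the other 3 groups, with an SE near 0.16 for the typical gene. HSP12 (3.22, SE 0.31, adjusted p = 2.75e-05), ADH4 (3.09, SE 0.30, adjusted p = 3.2e-05), HPF1 (2.99, SE 0.42, adjusted p = 0.00063) and TAF9 (2.76, SE 0.22, adjusted p = 4.97e-06) were higher in the mutant without SM. FAR1 (-2.87, SE 0.14, adjusted p = 4.53e-08) and PHO3 (-2.84, SE 0.21, adjusted p = 3.73e-06) were lower. URA3 is left out here, because it was not well above background on the arrays of taf9-tCRD2 with against without SM, which this comparison uses. Of 10 arginine genes 6 were higher, 8 adjusted within the list, and 4 did not pass (median 0.82, slides 0.80 and 0.67, adjusted p = 1.06e-05, or 0.0788 with an estimated correlation). Of 7 a-cell genes 5 were lower and 2 did not pass (median -1.10, slides -0.92 and -1.28, adjusted p = 3.37e-07). The a-cell list had adjusted p = 0.071 with an estimated correlation. Of 32 respiratory chain genes 7 were higher, 14 adjusted within the list, and 25 did not pass (median 0.48, slides 0.37 and 0.73, adjusted p = 6.13e-08). The respiratory list had adjusted p = 0.2 with an estimated correlation. Among stress response genes 8 of 53 were higher, 10 adjusted within the list, and 45 did not pass (median 0.48, slides 0.38 and 0.57, adjusted p = 6.24e-06). The stress response list had adjusted p = 0.74 with an estimated correlation. Over all genes 202 were higher and 274 lower, a total of 476, but the count moved from 867 on slide 1 to 176 on slide 2 (733 with the slide as a block), and was 967 with scaling and 70 with the dye-swapped arrays averaged. Camera called 13 lists, and with an estimated correlation 0, although 6 had an unadjusted p under 0.05.

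The last group asked which genes depend on Spt20 under starvation. Besides LEU2, URA3 and SPT20, the lowest genes in spt20D were ARO10 (51.6-fold lower, -5.69 ± 0.44, n = 2, adjusted p = 1.82e-12) and ARO9 (19.8-fold lower, -4.30 ± 0.48, adjusted p = 3.49e-10), both of aromatic amino acid breakdown, then PHO84 (-3.92 ± 0.34, adjusted p = 0.00126), the phosphatase gene PHM8 (-3.62 ± 0.66) and ASG7 (-3.56 ± 0.16). The highest were CIT2 (at least 15.3-fold, 3.93 ± 0.15, adjusted p = 1.79e-09), BOP2 (8.95-fold, 3.16 ± 0.24, adjusted p = 5.97e-09), ADH2 (7.69-fold, 2.94 ± 0.12, adjusted p = 5.54e-07), the cell wall protein gene TIP1 (2.39 ± 0.06), SER3 of serine synthesis (2.25 ± 0.50) and HMS1 (2.24 ± 0.10). ENA2 (2.22 ± 0.44) and THI5 (2.10 ± 0.14) belong to near-identical families. GCN4 did not pass (-0.01 ± 0.27, adjusted p = 0.976), nor did ARG1 (-0.09 ± 0.53, adjusted p = 0.704, saturated). HIS4 fell by 0.97 ± 0.04 (adjusted p = 0.000294). ILV2 stood at -0.69 ± 0.52 (adjusted p = 0.00364, but -0.52 and adjusted p = 0.14 without the second array).

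Several lists of amino acid synthesis genes were lower in spt20D in SM, relative to the typical gene. Spike-in RNA stood at -1.40 relative to the median gene on these arrays (SE 0.348, n = 2), so scaling to it would turn the direction of every lower list median above that value. All spt20D arrays lay on slide 2, so the medians in brackets are with the slide as a block. Of 12 branched-chain genes 10 were lower and 2 did not pass (median -1.07, block -1.03, adjusted p = 7.35e-06, or 0.0544 with an estimated correlation), among them BAT2 (-2.68 ± 0.02), OAC1 (-2.38 ± 0.27) and the mitochondrial aminotransferase gene BAT1 (-1.83 ± 0.01). Of 10 arginine genes 7 were lower and 3 did not pass (median -0.54, block -0.56, adjusted p = 0.000378, or 0.107 with an estimated correlation), with ARG3 at -1.92 ± 0.13 and ARG8 at -1.46 ± 0.27. Of 8 lysine genes 7 were lower and 1 did not pass (median -0.61, block -0.46, adjusted p = 0.00201, or 0.299 with an estimated correlation), with LYS9 at -1.98 ± 0.27. Of 13 aromatic genes 9 were lower and 4 did not pass, and 1 was higher adjusted within the list (median -0.66, block -0.59, adjusted p = 0.000292). The aromatic list had adjusted p = 0.218 with an estimated correlation. Of 6 histidine genes 4 were lower and 2 did not pass (median -0.51, block -0.49, adjusted p = 0.0217). The histidine list had adjusted p = 0.288 with an estimated correlation. Of 35 other Gcn4-activated genes 17 were lower, 3 higher and 15 did not pass, and adjusted within the list 18 were lower and 4 higher (median -0.33, block -0.31, adjusted p = 0.00158, or 0.218 with an estimated correlation), among them the alanine aminotransferase gene ALT1 (-2.78 ± 0.00) and the cyclin gene PCL5 (-1.44 ± 0.06). The lists of sulfur amino acid genes (7 higher, 6 lower and 9 not passing, 8 higher adjusted within the list, median 0.25, block 0.23, adjusted p = 0.388) and of threonine, homoserine and serine genes (2 higher, 6 lower and 7 not passing, 7 lower adjusted within the list, median -0.30, block -0.25, adjusted p = 0.0931) did not pass. With an estimated correlation their adjusted p-values were 0.737 and 0.496.

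Mating genes were lower in spt20D as well. All 7 a-cell genes were lower (median -2.37, block -2.46, adjusted p = 5.25e-07, or 0.0358 with an estimated correlation), among them BAR1 (-3.44 ± 0.17) and the a-factor gene MFA1 (-2.80 ± 0.10). Of 18 haploid and pheromone-induced genes 15 were lower, 1 higher and 2 did not pass, and 2 were higher adjusted within the list (median -1.38, block -1.46, adjusted p = 2.79e-07, or 0.0358 with an estimated correlation), with PRM1 at -3.12 ± 0.11 and FUS1 at -2.82 ± 0.16. Of 5 auxotrophic marker genes 4 were lower and 1 did not pass (median -1.20, block -1.16, adjusted p = 0.000176). The marker list had adjusted p = 0.0358 with an estimated correlation. Of 18 sporulation genes, usually silent in haploid cells, 11 were higher, 1 lower and 6 did not pass (median 0.44, block 0.47, adjusted p = 0.00119, or 0.0358 with an estimated correlation), among them DIT1 of the spore wall (1.27 ± 0.07) and HOP1 of meiosis (0.99 ± 0.08). Of the 20 lists that camera called in spt20D, these 4 held with an estimated correlation.

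Carbon metabolism moved in parts in spt20D. Of 20 gluconeogenesis and glyoxylate genes 15 were higher, 2 lower and 3 did not pass (median 0.77, block 0.71, adjusted p = 1.49e-05, or 0.218 with an estimated correlation), with the regulator gene ADR1 at 1.82 ± 0.22 and the malate synthase gene MLS1 at 1.29 ± 0.02. Of 32 respiratory chain genes 16 were higher, 1 lower and 15 did not pass, and adjusted within the list 17 were higher and 2 lower (median 0.38, block 0.38, adjusted p = 0.00488). The respiratory list had adjusted p = 0.484 with an estimated correlation. NDE1, a mitochondrial NADH dehydrogenase gene, stood at 1.60 ± 0.26, and the low-oxygen subunit gene COX5B at -2.12 ± 0.06. Of 15 hexose transporter genes 8 were higher, 1 lower and 6 did not pass, and 9 were higher adjusted within the list (median 0.77, block 0.66, adjusted p = 0.00304, or 0.367 with an estimated correlation), with HXT10 at 1.80 ± 0.23. Of 19 glycolysis genes 9 were lower and 10 did not pass (median -0.46, block -0.47, adjusted p = 0.0129, or 0.288 with an estimated correlation), with the enolase gene ENO1 at -1.53 ± 0.26. Ribosome biogenesis genes were higher in 53 of 102 cases, 2 were lower and 47 did not pass, and 55 were higher adjusted within the list (median 0.66, block 0.97, adjusted p = 4.48e-06). That list had adjusted p = 0.687 with an estimated correlation. Over all genes 1446 were higher and 1390 lower in spt20D, a total of 2836 (2991 with the slide as a block and 2709 on slide 2), and 186 were higher and 357 lower by at least 2-fold. With 1 spt20D array left out the total fell to 1380 or 1461, and with dye-swapped pairs of a slide averaged it was 1808.

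**Figure D2:**
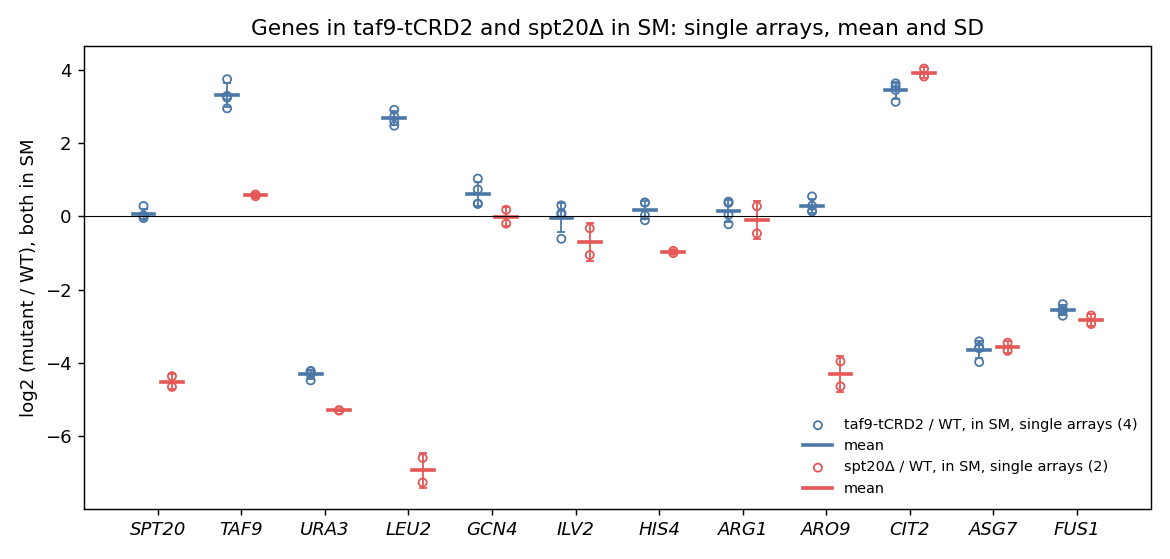
The log2 ratios of 12 genes in taf9-tCRD2 against WT (4 arrays) and in spt20D against WT (2 arrays), all in SM, are drawn as single arrays with their mean and SD. SPT20 lay at -4.51 in spt20D and 0.07 in taf9-tCRD2, TAF9 at 3.31 in taf9-tCRD2, and CIT2 at 3.45 and 3.93 in taf9-tCRD2 and spt20D.

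**Figure D3:**
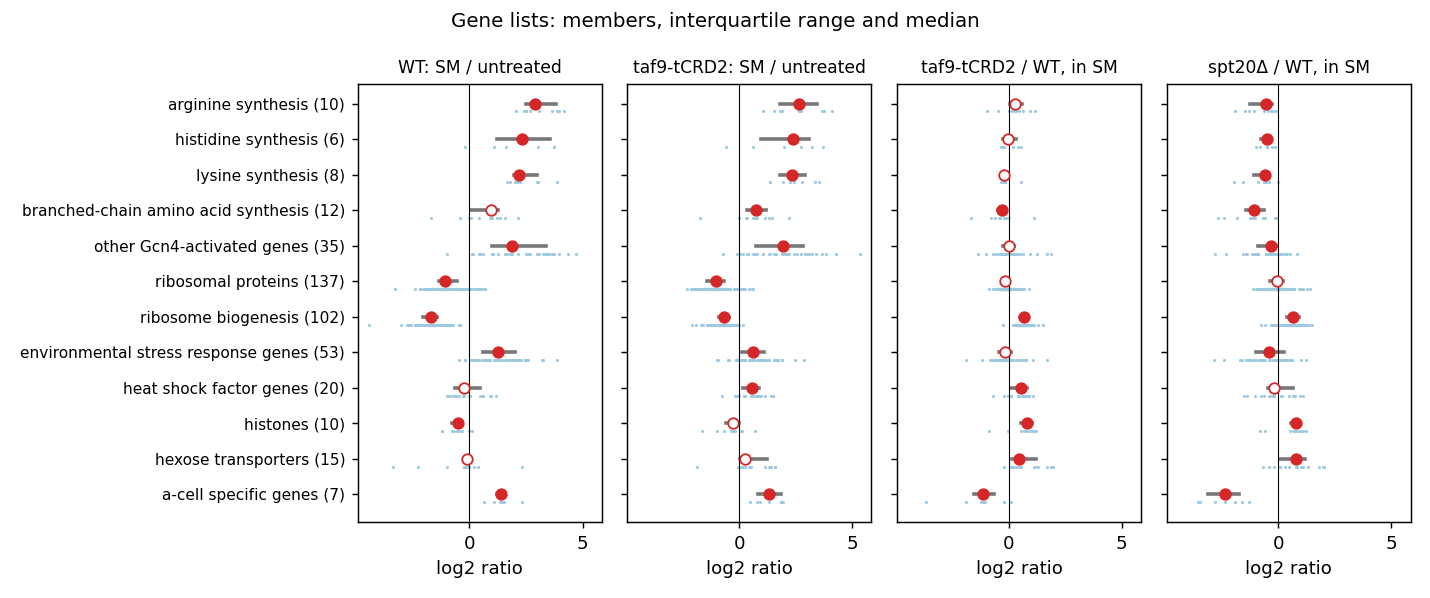
Points are members of 12 gene lists, with the log2 ratio on the horizontal axis, in the 4 measured comparisons, with a bar for the interquartile range and a large circle for the median, filled where camera with the preset correlation passed. The ribosome biogenesis median was -1.70 and -0.66 with SM in WT and taf9-tCRD2 and 0.66 in each mutant against WT in SM, and the branched-chain median was -1.07 in spt20D.

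Both mutants were then set side by side in SM through the difference of their effects, relative to the typical gene. The spike-in shift of spt20D minus that of taf9-tCRD2 was -1.51 (SE 0.400), and all 23 list medians below 0 stood above it, so scaling to spike-ins would turn them. ARO10 (-5.82, SE 0.15, adjusted p = 1.95e-11) and ARO9 (-4.58, SE 0.19, adjusted p = 2.15e-09) were lower in spt20D than in taf9-tCRD2, and BOP2 (2.40, SE 0.19, adjusted p = 1.48e-06), PUT4 (2.36, SE 0.19, adjusted p = 1.78e-06), GDS1 (2.10, SE 0.17, adjusted p = 1.7e-06) and the permease gene SEO1 (1.92, SE 0.15, adjusted p = 1.7e-06) were higher. The effect on 6 of 10 arginine genes was lower in spt20D and 4 did not pass (median -1.24, block -1.25, slide 2 -1.12, adjusted p = 1.69e-05, or 0.0664 with an estimated correlation), with ARG3 at -2.22 (SE 0.23). It was lower for 10 of 12 branched-chain genes, with 2 not passing (median -0.75, block -0.72, slide 2 -0.71, adjusted p = 1.69e-05, or 0.0664 with an estimated correlation), among them ILV5 (-1.73, SE 0.24) and BAT1 (-1.65, SE 0.18). Glycolysis genes had 11 lower, 12 adjusted within the list, and 8 not passing (median -0.67, block -0.67, slide 2 -0.60, adjusted p = 3.05e-05, or 0.0664 with an estimated correlation), with ENO1 at -1.89 (SE 0.22). Purine genes had 11 lower, 2 higher and 5 not passing (median -0.90, block -0.79, slide 2 -0.78, adjusted p = 7.21e-05, or 0.302 with an estimated correlation), with ADE17 at -2.42 (SE 0.10). Of 7 a-cell genes 5 were lower in spt20D than in taf9-tCRD2 and 2 did not pass (median -1.41, block -1.53, slide 2 -1.53, adjusted p = 0.000578). The a-cell list had adjusted p = 0.141 with an estimated correlation. Respiratory chain genes had 10 higher, 13 adjusted within the list, 1 lower and 21 not passing (median 0.38, block 0.41, adjusted p = 0.00523, or 0.402 with an estimated correlation), but on slide 2 the median was 0.27 and the adjusted p 0.0627. Sulfur amino acid genes had 11 higher, 12 adjusted within the list, 2 lower, 4 adjusted within the list, and 9 not passing (median 0.39, block 0.40, adjusted p = 0.0266, or 0.326 with an estimated correlation). This call was lost on slide 2 (0.29, adjusted p = 0.0566) and without the first spt20D array (0.38, adjusted p = 0.061). Over all genes 844 were higher and 792 lower, a total of 1636 (1756 with the slide as a block, 1171 on slide 2), and 695 without the first spt20D array or 805 without the second. Camera called 18 lists, and 1 of them with an estimated correlation.

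The final question was what share of the genes induced by SM depends on each factor. Of 718 genes that rose at least 2-fold in WT, 348 were lower in taf9-tCRD2 in SM (48.5%, exact 95% interval 44.8% to 52.2%) and 76 were higher (10.6%). In spt20D 373 were lower (51.9%, interval 48.2% to 55.7%) and 67 higher (9.33%), relative to the typical gene. Of the 373 lower ones 282 stood above the spike-in shift of -1.40, so scaling to spike-ins would turn their direction. If induction and the mutants' effects were independent over all genes, 160.1 and 165.8 would have been lower. Both mutants lowered 241 of them (33.6%, interval 30.1% to 37.2%), against 180.8 if the calls of both mutants were independent among these genes, and 177 of the 241 stood above that shift in spt20D. These shares share RNA with the list they are taken from, since noise that raises the WT RNA with SM puts a gene on the list and lowers it in both mutants. In simulated data with mutants without any effect, 10.4% of induced genes were lower in taf9-tCRD2, 8.74% in spt20D and 2.98% in both. The shares were 59.3% for taf9-tCRD2 on slide 1 and 35.5% on slide 2, and 56.8% for spt20D and 37.7% for both with the slide as a block (51.4% and 26.1% on slide 2). With scaling between arrays they were 54.7%, 59.7% and 40.6%. SM-induced genes also responded less in taf9-tCRD2 in 347 cases (48.3%, simulated 11.1%) and more in 24 (3.34%). This share did not hold: it was 12.3% with scaling, 16.2% with dye-swapped pairs of a slide averaged, and 70.8% on slide 1 but 19.3% on slide 2. Of 700 genes that fell at least 2-fold, 258 were higher in taf9-tCRD2 (36.9%) and 213 in spt20D (30.4%).

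Over all genes the effects of both mutations in SM correlated with r = 0.483, against a mean of 0.354 (range 0.306 to 0.400) in the simulated data with no effects, where the correlation comes from the shared WT RNA alone. The covariance was 0.136 against 0.0122. With taf9-tCRD2 arrays of slide 1, which share no slide with the spt20D arrays, r was 0.477 and the covariance 0.145, and with those of slide 2 they were 0.430 and 0.127. In all, relative to the typical gene, 708 genes were lower in both mutants (615 of them above the spike-in shift in spt20D, 310 if independent, 133.2 simulated) and 662 were higher in both (314 if independent, 129.8 simulated), while 105 and 122 moved in opposite directions (322 and 302 if independent). The simulation covers RNA noise of the arrays' size, but no larger difference of WT cultures, which both comparisons would carry.

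**Figure D4:**
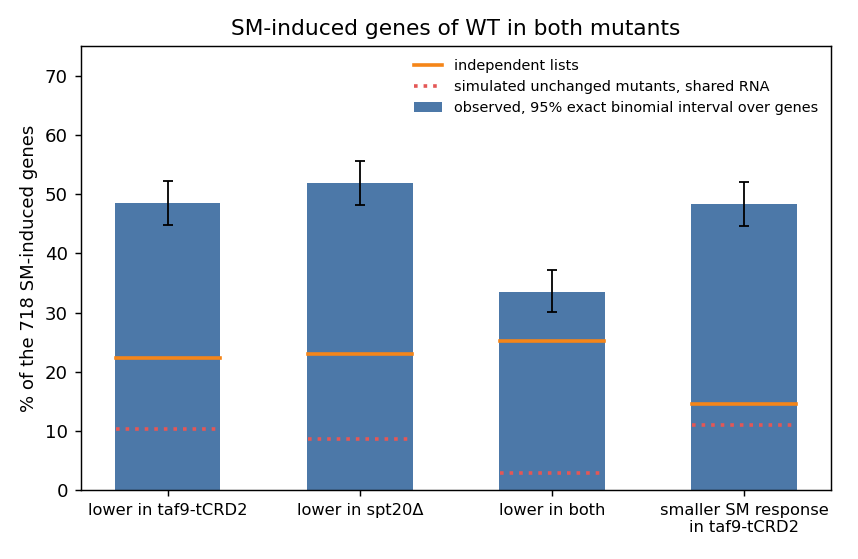
Bars give the percentage of the 718 SM-induced genes that were lower in taf9-tCRD2, in spt20D and in both in SM, and that responded less to SM in taf9-tCRD2, with exact 95% binomial intervals. The bars stand at 48.5%, 51.9%, 33.6% and 48.3%, the orange line shows what independent calls would give, and the dotted red line shows simulated mutants without any effect (10.4%, 8.74%, 2.98% and 11.1%). The last bar fell to 12.3% with scaling.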

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

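Of the tests in this part, the comparison of ribosomal proteins with ribosome biogenesis genes and the tests of explanations for a-cell and branched-chain genes were chosen after the results they bear on were seen. The other normalizations and the single slides were planned.

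SM lowered ribosome biogenesis genes less in taf9-tCRD2 than in WT (median difference 1.06), and the same held for RNA polymerase I and III genes (0.57), with adjusted p = 0.495 for each list with an estimated correlation. A product of the loess normalization is argued against by the median of 1.00 that the lower of median centring and Feature Extraction ratios gave (0.66 with scaling), and a slide effect by the median of 0.87 on the lower slide. A common shrinking of all ratios on the mutant arrays is argued against because the ribosomal protein list kept 0.949 of its WT response and ribosome biogenesis 0.386, a gap of 0.564. Strain background and a lasting effect of the mutant's denser start stay open, untested. All cultures were labelled equally dense at SM addition. As 1 hypothesis among these, the C-terminal region of Taf9 may take part in lowering these genes.

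Genes of a cells were lower in both mutants in SM (median -1.12 in taf9-tCRD2 and -2.37 in spt20D, and a difference of -1.41 between them), though with an estimated correlation only spt20D passed (adjusted p = 0.332, 0.0358 and 0.141). Alpha cells in the cultures are argued against because alpha-specific genes had a median of -0.062 in spt20D and -0.08 in taf9-tCRD2. Diploid cells as the whole cause are argued against because 6 other haploid genes had a median of -1.02 in spt20D (range -1.56 to 0.30), above that of the a-cell list, but as a part they stay open, since the sporulation list was higher there (0.44) and the haploid and pheromone list lower (-1.38), as diploid cells would have it. A high level in the WT RNA with SM alone is argued against for taf9-tCRD2 by the difference in SM response, whose median was 0.31 (mean -0.08, not passing), but not for the haploid and pheromone list, which responded less (-0.34, adjusted p = 0.0219, not passing on slide 2 or with scaling), and for spt20D no untreated arrays exist. Strain background stays open, since the strains differed in URA3 as well, so a role of Taf9 and Spt20 at these genes may only be put as a hypothesis.

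Branched-chain genes were lower in spt20D in SM, and lower than in taf9-tCRD2 (median difference -0.75), with adjusted p = 0.0544 and 0.0664 with an estimated correlation, and both only relative to the typical gene, since scaling to spike-ins (-1.40 in spt20D) would turn them. That noise in the shared WT RNA made this is argued against by the difference between both mutants on slide 2 alone, whose median was -0.71. A changed leucine pool that acts through the regulator Leu3 cannot be told apart from an effect of the deletion. The 7 Leu3 targets had a median of -0.93 against -0.57 for 24 arginine, histidine and lysine genes (two-sided permutation p = 0.168). So few genes leave this gap open. LEU2 RNA was near background in spt20D, at -9.62 relative to taf9-tCRD2. How such a lack would move the Leu3 targets was not tested. Such a strain in a medium lacking leucine, as labelled, is odd enough that the strain or the medium may not be as labelled. All spt20D arrays lay on 1 slide, so the slide cannot be separated from this group except through a shared WT RNA.

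Other gene lists differed in SM response between taf9-tCRD2 and WT by camera with its preset correlation, while with an estimated correlation none passed (adjusted p from 0.495 to 0.619 for those named). Heat shock factor genes (0.65), hexose transporters (0.42) and purine synthesis (0.42) had a higher median response in the mutant. Stress response genes (-0.56), the respiratory chain (-0.48), nitrogen catabolite repression genes (-0.41) and aromatic amino acid genes (-0.24) had a lower one. So had arginine genes (-0.44, but 0.038 with scaling between arrays) and other Gcn4-activated genes (-0.27, but 0.13 with scaling, and not passing without taf9-tCRD2 array 4 at -0.23).

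Single genes differed in the same way, upward for URA1 (2.76), HXT4 (2.75), HXT3 (2.58), CIT2 (2.56), DBP2 (2.54), NSR1 (2.23), NOG1 (2.06), LEU2 (1.54, with saturated signals), YDJ1 (1.36) and SNZ1 (0.98, saturated in taf9-tCRD2, so not an exact size). They differed downward for ADH4 (-2.71), ALD3 (-2.17), HSP12 (-2.16), PUT4 (-2.03) and GDH2 (-1.47). ARG1 stood at -1.44, but its probe was saturated with SM, which caps the responses of both strains, so its size and direction are uncertain. ZPS1 stood at -2.41, but did not pass without WT array 3 (-1.82) or 4 (-1.92) or taf9-tCRD2 array 1 (-2.19) or 2 (-2.25). ILV2 stood at 0.61 (0.54 and adjusted p = 0.0506 without the first taf9-tCRD2 array). TAF9 stood at 0.55, but at -0.22 with median centring, and it did not pass without WT array 1 (0.57), 2 (0.48) or 4 (0.44) or taf9-tCRD2 array 1 (0.52), 2 (0.52) or 4 (0.48). HIS4 stood at -0.51, but its probe too was saturated with SM, it was at 0.17 with scaling, and it did not pass without WT array 1 (-0.46), 2 (-0.53) or 4 (-0.48) or taf9-tCRD2 array 1 (-0.37), 2 (-0.53) or 3 (-0.50).

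The effects of both mutations in SM also differed by a test of the difference. As lists, by camera with its preset correlation and relative to the typical gene (spike-ins, at -1.51 in this difference, would turn the lower ones), arginine (-1.24), purine (-0.90) and glycolysis genes (-0.67) were lower in spt20D than in taf9-tCRD2, and respiratory chain (0.38) and sulfur amino acid genes (0.39) were higher, the last 2 not passing on slide 2 alone and sulfur genes not without spt20D array 1 (0.38). With an estimated correlation these lists had adjusted p = 0.0664, 0.302, 0.0664, 0.402 and 0.326. As genes, BOP2 (2.40), PUT4 (2.36), GDS1 (2.10) and SEO1 (1.92) were higher. ARO10 (-5.82), ARO9 (-4.58), ADE17 (-2.42), ARG3 (-2.22), ENO1 (-1.89), ILV5 (-1.73) and BAT1 (-1.65) were lower. SPT20 stood at -4.58, a size that depends on the background correction since its signal in spt20D was not well above background. GCN4 stood at -0.62 (adjusted p = 0.0287), but did not pass without the first taf9-tCRD2 array (-0.54) or either spt20D array (-0.63 and -0.61).

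Among 118 values of named genes and 44 list medians, each over 4 arrays, 5 genes and 1 list had a single array far from the other 3, while chance gives about 1 in 20. With SM in WT, SAH1 stood at -2.80 on array 2 against a mean of -3.45 on the others, AGP1 at 2.27 on array 4 against 2.79, and the gluconeogenesis list at 0.94 on array 3 against 0.79. With SM in taf9-tCRD2, HSP78 stood at 2.11 on array 2 against 3.1. In taf9-tCRD2 against WT, HHT2 stood at 0.89 on array 1 against 0.60, and HXT3 at 2.22 on array 1 against 1.88.

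Spike-in Cy3 signal was 105 times that of negative control spots (median, arrays 39.3 to 205).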

How the results depend on the processing

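Averaging the dye-swapped arrays of a slide was chosen after seeing the data, and the other tests were planned. Apart from the camera test with an estimated correlation and fry, of 115 list medians that passed, 83 kept direction and call in every setting, 32 lost the call in some and 7 turned in some; of 421 named gene values these were 338, 83 and 5. The cause of the changes below was not tested, except that slides alone, averaged pairs and left-out arrays use fewer arrays and fold minimums admit fewer genes. At least 2-fold, counts were 1418 (SM in WT), 942 (SM in taf9-tCRD2), 211 (taf9-tCRD2 against WT in SM), 543 (spt20D), 268 (difference in response), 121 (untreated) and 393 (difference of effects), and at least 1.5-fold 2716, 2171, 826, 1513, 812 and 1040, the untreated one staying within 1.5 times. Shares of SM-induced genes lower in taf9-tCRD2, spt20D and both (48.5%, 51.9% and 33.6%) became 54.7%, 59.7% and 40.6% with scaling, 37.6%, 41.8% and 25.2% with averaged pairs, and 40.9%, 39.6% and 25.5% with induction counted from 1.5-fold. For spt20D and both they were 44.8% and 29.8% with Feature Extraction ratios, 44.8% and 29.7% with the deposited table, 46.4% and 30.0% with median centring, and 56.8% and 37.7% with the slide as a block. The spt20D share was 47.6% without a dye term, and that of taf9-tCRD2 was 42.1% when only the arrays of a contrast were fitted, 59.3% on slide 1 and 35.5% on slide 2, where that of both was 26.1%. Scaling gave 442 genes for the difference in response and 967 untreated. The untreated count was 733 with the slide as a block, 867 on slide 1 and 176 on slide 2, where taf9-tCRD2 against WT gave 1517 genes and 19 lists and the difference in response 572. Averaged pairs (3 residual degrees of freedom) gave 1589 genes for taf9-tCRD2, 1808 for spt20D, 281 for the difference in response, 70 untreated and 661 for the difference of effects. Camera with an estimated correlation called 0 lists with SM in WT, with SM in taf9-tCRD2, in taf9-tCRD2 against WT, in the difference and untreated (7, 7, 2, 1 and 6 at an unadjusted p under 0.05), 4 in spt20D and 1 in the difference of effects; fry called 32, 33 and 22 in the first 3.

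Directions turned as follows. With median centring, SM in taf9-tCRD2 gave -0.11 for the heat shock factor list, -0.075 for ARG1 and -0.067 for TRP1, and the difference in response of TAF9 was -0.22. With scaling, the difference in response was 0.038 for the arginine list, 0.13 for other Gcn4-activated genes and 0.17 for HIS4, the untreated medians were -0.083 for other Gcn4-activated genes, 0.24 for ribosome biogenesis and 0.048 for translation factors, and the difference of effects on URA3 was 0.044. On slide 2 alone the untreated median of other Gcn4-activated genes was -0.0066, and without the second taf9-tCRD2 array in SM the glycolysis median was -0.0096 (0.16 without any 1 of the other arrays of that group). With the replicate block, no count moved by over 1.5 times: 4605, 4296, 2834, 2757, 1835, 600 and 1719 genes in the order above, r = 0.886, shares of 50.4%, 48.9% and 32.7%, and 19, 18, 13, 21, 16, 14 and 21 lists.

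Leaving out each array in turn gave 4282 to 4358 genes with SM in WT, 3796 to 4013 with SM in taf9-tCRD2, 2060 to 2407 for taf9-tCRD2 against WT, 1380 to 1461 for spt20D, 1152 to 1911 for the difference in response, 347 to 607 untreated and 695 to 1647 for the difference of effects. A lone spt20D array was assumed to vary like the other groups. The correlation r ran from 0.855 to 0.899, and the shares from 41.4% to 50.0%, 35.7% to 53.5% and 24.9% to 34.4%. Lists passing ran from 18 to 18, 18 to 19, 9 to 14, 19 to 20, 15 to 16, 12 to 17 and 16 to 18 in the same order. Fitting only the arrays of the contrast was impossible for spt20D, whose 2 arrays leave no residual degrees of freedom with a dye term. Choosing the brightest probe had no object with 1 probe per gene. Dim and saturated probes limited single genes, such as URA3, SPT20, HIS4 and ARG1, more than the counts.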

Other observations

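The tests on genes near chromosome ends were chosen after the results they bear on were seen, and those on spike-ins and regrouped arrays were planned.

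In spt20D in SM, cell wall genes were lower in 17 of 26 cases, higher in 4 and did not pass in 5 (median -0.73, with the slide as a block -0.76, adjusted p = 0.00304 in limma's camera). The cell wall list had adjusted p = 0.496 with an estimated correlation. Among them were the cell wall protein gene CWP2 (-1.16 ± 0.34, n = 2) and SLT2, the kinase gene of the cell integrity pathway (-1.10 ± 0.23). Of 33 proteasome genes 16 were lower, 2 higher and 15 did not pass, and 3 were higher adjusted within the list (median -0.24, block -0.22, adjusted p = 0.00725, or 0.593 with an estimated correlation), with PRE1 at -0.87 ± 0.34 and PUP2 at -0.84 ± 0.12. Of 20 tricarboxylic acid cycle genes 11 were higher, 3 lower and 6 did not pass (median 0.39, adjusted p = 0.0193, or 0.484 with an estimated correlation), with the citrate synthase gene CIT1 at 1.49 ± 0.07, but with the slide as a block the median was 0.28 and the adjusted p 0.0552. Of 10 histone genes 8 were higher and 2 lower (median 0.77, block 0.85, adjusted p = 0.0399, or 0.484 with an estimated correlation), with HHT2 at 1.09 ± 0.10, and this call was lost without the second array (0.68, adjusted p = 0.069). Of 53 stress response genes 20 were lower, 4 higher and 29 did not pass (median -0.42, block -0.82, adjusted p = 0.0294, or 0.787 with an estimated correlation), and this call was lost without the first array (-0.50, adjusted p = 0.0635).

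Untreated taf9-tCRD2 cells differed from WT in further lists. Of 20 tricarboxylic acid cycle genes 5 were higher, 8 adjusted within the list, and 15 did not pass (median 0.36, slides 0.25 and 0.54, adjusted p = 2.89e-06). That list had adjusted p = 0.18 with an estimated correlation. Of 18 haploid and pheromone-induced genes 10 were lower and 8 did not pass, and adjusted within the list 11 were lower and 1 higher (median -0.63, slides -0.62 and -0.64, adjusted p = 3.37e-07). The haploid and pheromone list had adjusted p = 0.071 with an estimated correlation. Of 102 ribosome biogenesis genes limma called 0, although 7 were lower at an unadjusted p under 0.05, and the list's median of -0.38 (slides -0.29 and -0.46, adjusted p = 3.64e-05, or 0.786 with an estimated correlation) became 0.24 with scaling. That median was -0.21 without WT array 3, -0.18 and -0.64 without arrays 1 and 4 of taf9-tCRD2 with against without SM, and -0.22 without array 4 of taf9-tCRD2 against WT.

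Genes near chromosome ends were looked at because several of the genes that rose in spt20D lie there. The hypothesis that the position itself goes with a rise in spt20D was argued against: 412 genes within 30 kb of the outermost probes had a median of 0.052 in spt20D, at percentile 77.4 of 10000 random gene sets of like brightness, with 124 higher and 96 lower. In taf9-tCRD2 against WT in SM, however, these genes had a median of -0.18, below all random sets, whose lowest was -0.07 (-0.20 on slide 1 and -0.16 on slide 2, 61 genes higher and 182 lower). With SM in WT their median was 0.31, above all random sets, whose highest was 0.12 (0.26 and 0.30 on the slides, 228 higher and 85 lower). The taf9-tCRD2 and WT values share the WT RNA with SM, so they are not independent of each other.

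Spike-in RNA was used to test whether SM changed the share of mRNA in the labelled RNA, which the normalization hides. In the WT arrays spike-ins shifted by -0.03 relative to the median gene (SE 0.230, n = 4), which is 0.131 SE. The bound of 2 SE set for excluding a change leaves large shifts open, so the test decides nothing. The shift was -0.18 in taf9-tCRD2 with against without SM (SE 0.225, n = 4) and 0.11 in taf9-tCRD2 against WT (SE 0.198, n = 4). In spt20D against WT it was -1.40 (SD 0.492, SE 0.348, n = 2), or 4.03 SE, with both arrays below 0. Scaled to spike-ins instead of the typical gene, the lower spt20D list medians above -1.40 would turn, so their direction holds only relative to the typical gene.

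Turning the sign of arrays, or regrouping them, tested whether other groupings of the same arrays give as many genes in limma. With SM in WT, SM in taf9-tCRD2 and taf9-tCRD2 against WT, 1 of 8 sign patterns, the real one, gave as many genes (4581, 4241 and 2648, against at most 3, 2 and 1 in the others), but 8 patterns are too few for a share under 0.05. For the difference in SM response, 1 of 35 splits of the 8 arrays, the real one, gave 1679 genes or more, and the highest other gave 105. That share excludes chance only if the arrays are independent. They are dye-swapped arrays on 2 slides that may share cultures, averaging those of a slide left 281 genes, and with such pairs as units the splits are too few for a share under 0.05.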
